A study of Gallus gallus with 200 samples.

How the data were processed

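Blood DNA of 200 Qiangyuan Partridge chickens, 100 with white and 100 with red earlobes, was genotyped by specific-locus amplified fragment sequencing (SLAF-seq), which reads a size-selected part of the genome cut by a restriction enzyme, here HaeIII. Per the labels' protocols, fragments of 364 to 444 bp were predicted from the Gallus_gallus 4.0 genome, libraries were read on an Illumina HiSeq instrument, and 622443 markers, 424810 of them polymorphic, had a mean depth of 10.03-fold. BWA, SAMtools and GATK are named in the submitters' processing notes without a version. The genome build of the SNP positions, the filters and the depth of each genotype are not given in the sources used here. At such a depth some heterozygotes are read as homozygotes, and alleles of a cut site that is lost drop out, both of which lower heterozygosity.

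The deposited genotype table, made by the authors, holds 1 letter per SNP and bird, a base for a homozygote, an ambiguity code for a heterozygote and N for no call, per the file headers and values. The lowest minor allele frequency in it was 0.05 and all but 2 SNPs were called in at least 80% of birds, so that filters had been set before deposit. A second table deposited by the authors holds 1 unadjusted p-value per SNP, from a PLINK case-control model per the series' design text. No genotype column was left without a labelled bird. Each column was matched to a bird by the number in the labels, and the colour was taken from the labels. The labels give no sex, family, farm or sequencing batch. Birds are the replicates; nothing in the labels says whether they were related. Apart from the mixed model, p-values treat them as independent, although 180 of 19900 pairs had a genomic relationship over 0.2.

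From the genotypes, the rarer base was counted as 0, 1 or 2 per bird. SNPs with call rate of at least 0.8 and minor allele frequency of at least 0.05 were tested, 223796 in all. The test was the allelic chi-square test with 1 degree of freedom, two-sided, without covariates, with Bonferroni and Benjamini-Hochberg thresholds of 0.05. Regions joined SNPs past Bonferroni whose neighbours lay within 500 kb, and the SNP with the smallest p led each. Named are the leads of the 10 regions with the smallest p and the 5 windows with the highest FST, a rule fixed before the data were examined, as were the tests and the alternatives, except those said to be added. The allele frequency errors are binomial, and the intervals of odds ratios come from allele counts. Both treat the alleles of a bird as independent, which is too narrow where heterozygotes are missing, and on Z where a hen's single allele is counted as 2. FST was Hudson's ratio of averages, with a jackknife over blocks of 1 Mb, and windows of 100 kb needed at least 5 SNPs. Principal components and the relationship matrix used autosomal SNPs with call rate of at least 0.9, at most 1 SNP per 10 kb. Values per bird were compared with permutation tests of 100000 resamples. The colour labels were shuffled 100 times. The deposited p-values were set against 5 models.

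Birds with under 15% heterozygous Z calls were taken to carry a single Z in an alternative that counts 1 allele for them. A principal component of the 740 SNPs with more heterozygotes than Hardy-Weinberg proportions give (exact p under 0.0001, call rate over 0.95, not on Z) was divided along the bird numbers, at 2 points in white-earlobe and 1 in red-earlobe birds, and the segments were merged into 3 runs by their means. The runs were found again without the sites of each of 34 sequences in turn, with the unplaced sequences as 1, to compare SNPs between runs that their own sequence had no part in. Terms for these runs, the analysis of single runs, the single-Z count, and the removal of near-identical or very heterozygous birds were added after seeing the data. Other alternatives were Fisher's exact test, the trend test, linear models with 5 principal components, Z heterozygosity or call rate, a mixed model (in which the variance share of kinship lay at 0.99, the top of the values tried), genomic control, filters on call rate and Hardy-Weinberg proportions, and thinning.

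The tests were tested on simulated data first. Among 50000 simulated SNPs in groups of the same size, 200 were changed, all with a minor allele frequency over 0.2. The allelic test recovered 0% of allele frequency differences of 0.1, 2% of 0.15, 18% of 0.2 and 54% of 0.25 at its Bonferroni threshold. The simulated birds were unrelated and in Hardy-Weinberg proportions, without the kinship and missing heterozygotes of the data. At such SNPs and in such birds smaller differences are thus mostly missed at this threshold. Recovery in the real birds was not measured. The median minor allele frequency in the data was 0.194, and recovery at rarer alleles was not simulated. Simulated Z genotypes with 141 single-copy birds and no group difference gave an inflation factor of 1.73 with 2 alleles for each bird and 0.988 with 1. Candidate gene lists (melanin pigmentation, purine metabolism and transport, carotenoid and retinoid pigmentation, blood vessel formation, haemoglobin and heme, dermal connective tissue and appendages, Z-linked and sex development) were chosen in advance but not run, since the gene table used here is of another assembly, GRCg7b, and no coordinate was taken from it. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.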

Results

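Genotypes were compared between 100 chickens with white earlobes and 100 chickens with red earlobes, all of the Qiangyuan Partridge breed and each genotyped from blood DNA. The earlobe is a bare fold of skin under the ear, and its colour is a breed mark in chickens. The question was which parts of the genome differ in allele frequency between birds of the 2 colours. The table held 223798 single-nucleotide polymorphisms (SNPs) that each carried 2 bases among the birds. Of these, 213441 lay on 30 numbered chromosomes, 5832 on the sex chromosome Z, 148 on the sex chromosome W, 5 on the mitochondrial genome and 4372 on 483 unplaced sequences. The lowest minor allele frequency was 0.05. On average 95.0% ± 3.38 (SD, n = 100) of the SNPs were called in a white-earlobe bird and 95.1% ± 2.13 (SD, n = 100) in a red-earlobe bird, with single birds from 74.3% to 98.6% (permutation p = 0.927 for the difference, two-sided). The files give no read counts per genotype, so the depth behind a single genotype is unknown. Positions are those of the deposited table, whose genome build is not given in the sources used here, and no gene could therefore be placed beside a SNP.

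White-earlobe and red-earlobe birds differed past the Bonferroni threshold of 2.23e-07 at 39 of 223796 tested SNPs, in 20 regions. The minor allele was more frequent in white-earlobe birds at 21 of the 39 SNPs and in red-earlobe birds at 18. Chromosome Z held 16 of them, chromosome 9 held 8, chromosome 20 held 4, chromosome 19 held 3 and chromosome 3 held 2. The remaining SNPs lay singly on chromosomes 2, 4, 10, 11, 13 and 23. At a false discovery rate of 0.05 (Benjamini-Hochberg), 1765 SNPs differed, 1013 of them with the minor allele more frequent in white-earlobe birds and 752 in red-earlobe birds. These counts are from the allelic chi-square test with 2 alleles for each bird. With 1 allele on Z for each bird with few heterozygous Z calls, 23 SNPs passed Bonferroni, none of them on Z. Under the genotype trend test 8 SNPs passed Bonferroni and 135 the false discovery rate, of which 3 and 130 were among those of the allelic test. In a mixed model that allowed for kinship 2 and 2 passed, of which 1 and 2 were among them. These lay on chromosome 19 at 3930351 (mixed model p = 2.00e-08) and on an unplaced sequence at 1311 (p = 8.79e-09). In 59 of 100 shuffles of the colour labels at least 1 SNP passed the Bonferroni threshold, with at most 5, and only 6 of the 39 SNPs passed the 5% threshold of 5.81e-09 that the shuffles gave. That threshold ignores that the birds fell into 3 runs by their numbers in the labels, of which 1 held white-earlobe birds only. In 50 shuffles within these runs, added later, it was 6.19e-10, which 1 SNP passed, and 1 of the 50 gave a p as small as 4.43e-12, under the smallest of the real split.

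**Figure D1:**
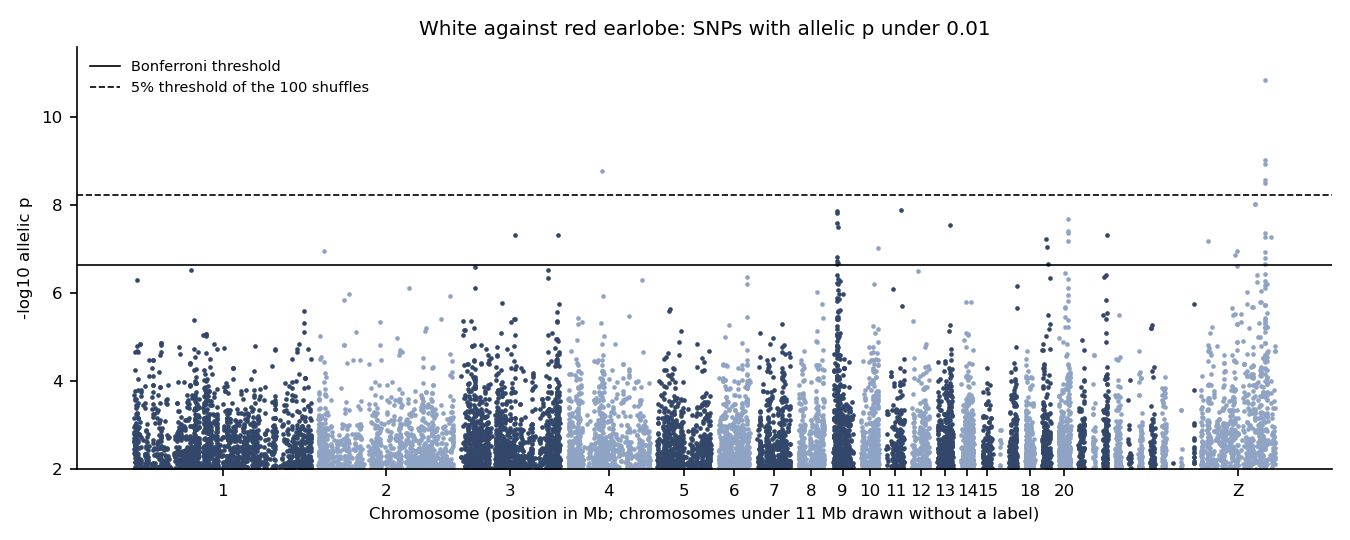
Allelic p (as -log10) of each SNP with p under 0.01 against its position, chromosome by chromosome, for white-earlobe against red-earlobe birds, with the Bonferroni threshold of 2.23e-07 as a solid line and the threshold of 5.81e-09 from 100 shuffles as a dashed line. The highest point is on Z, at 1.41e-11, and chromosome 9 carries a column of points above the solid line; the dashed line ignores runs of bird numbers, and shuffles within runs gave 6.19e-10.

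The region with the smallest p lay on chromosome Z from 70610425 to 71378423 and held 10 of the SNPs past Bonferroni. At its lead SNP (G70676051C, the common base first, then the position on the chromosome and the rarer base) the rarer allele made up 30.5% ± 3.26 (SE, n = 100 birds) of alleles in white-earlobe birds and 4.59% ± 1.5 (SE, n = 98) in red-earlobe birds. The allelic p was 1.41e-11, Fisher's exact p was 2.57e-12 and the odds ratio was 9.12 (95% interval 4.38 to 19.0). These count 2 alleles for each bird, so the interval is too narrow where birds carry a single Z. The rarer allele was carried by 35 of 100 white-earlobe birds and by 7 of 98 red-earlobe birds. The other SNPs of the region were weakly correlated with the lead (median r squared 0.0371, highest 0.174), and the minor allele was more frequent in white-earlobe birds at 4 and in red-earlobe birds at 6 of the 10. The lead of another Z region, at 59810111, had the rarer allele at 33.0% ± 3.32 (SE, n = 100) in white-earlobe birds and 9.50% ± 2.07 (SE, n = 100) in red-earlobe birds (allelic p = 9.21e-09). Hens carry a single Z, and counting 1 allele for each bird with few heterozygous Z calls raised the p of the leads to 3.36e-06 and 3.01e-06, so that neither passed Bonferroni. The allele frequencies were then 27.1% against 5.56% at the first lead and 34.4% against 10.2% at the second.

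Chromosome 9 carried 8 SNPs past Bonferroni in 2 neighbouring regions, and at all 8 the minor allele was more frequent in white-earlobe birds. In the region from 5603095 to 6024058, with 6 SNPs, the lead (G6024045T) had the minor allele at 41.7% ± 3.67 (SE, n = 90) in white-earlobe birds and 15.5% ± 2.56 (SE, n = 100) in red-earlobe birds (allelic p = 1.36e-08, odds ratio 3.89, 95% interval 2.40 to 6.32). In the region from 6897117 to 7072468, with 2 SNPs, the lead (G7072468A) stood at 25.0% ± 3.13 (SE, n = 96) against 5.05% ± 1.56 (SE, n = 99), with p = 3.10e-08 and an odds ratio of 6.27 (95% interval 3.07 to 12.8). No red-earlobe bird was homozygous for its minor allele, against 7 white-earlobe birds, and 34 white-earlobe and 10 red-earlobe birds were heterozygous. The leads lie 1048423 bp apart and were correlated across birds (r squared 0.345). The first lead had fewer heterozygotes than Hardy-Weinberg proportions give (exact p = 0.00112) and did not pass Bonferroni under the trend test (p = 3.44e-07). The second lead was in Hardy-Weinberg proportions (exact p = 0.151) and passed Bonferroni under the trend test too (p = 1.47e-07). In the mixed model its p was 2.15e-06 and that of the first lead 1.23e-05, and neither passed Bonferroni.

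The remaining 6 of the 10 regions named by the smallest lead p lay on 6 autosomes. The minor allele was more frequent in red-earlobe birds at chromosome 4 position 37988936, with 50.6% ± 3.86 (SE, n = 84) against 19.5% ± 3.01 (SE, n = 87) in white-earlobe birds (p = 1.66e-09). The same direction was seen at chromosome 11 position 15968035, with 23.8% ± 3.36 (SE, n = 80) against 2.87% ± 1.27 (SE, n = 87) (p = 1.26e-08), and at chromosome 20 position 10474884, with 52.9% ± 3.83 (SE, n = 85) against 23.6% ± 3.22 (SE, n = 87) (p = 2.02e-08). The chromosome 20 region held 4 SNPs and ran to 11207778. In white-earlobe birds the minor allele was more frequent at chromosome 13 position 14995483, with 56.6% ± 3.67 (SE, n = 91) against 27.1% ± 3.45 (SE, n = 83) in red-earlobe birds (p = 2.75e-08). So it was at chromosome 23 position 4268912, with 43.5% ± 3.51 (SE, n = 100) against 17.9% ± 2.78 (SE, n = 95) (p = 4.66e-08), and at chromosome 3 position 60979558, with 30.9% ± 3.32 (SE, n = 97) against 9.00% ± 2.02 (SE, n = 100) (p = 4.74e-08). Heterozygotes were fewer than Hardy-Weinberg proportions give at all 6 leads, with an exact p from 4.26e-15 to 1.55e-13 on chromosomes 4, 11, 13 and 20, of 2.66e-06 on chromosome 3 and of 0.00714 on chromosome 23. None of these 6 leads passed Bonferroni under the trend test.

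The numbers the labels give the birds fell into 3 runs on a principal component of 740 SNPs with too many heterozygotes. Run 1 held white-earlobe birds 1 to 30 and red-earlobe birds 101 to 129, run 2 held white-earlobe birds 31 to 81, and run 3 held white-earlobe birds 82 to 100 and red-earlobe birds 130 to 200. The runs took up 77.3% of the variance of that component, against at most 9.26% in 20 shuffled orders. It was chosen among the first 5 components as the one that runs explained best, and the shuffles did not repeat this choice. Run 2 has birds of 1 colour only, so the colours were compared again within runs 1 and 3. In each of these the colours hold separate ranges of bird numbers, so a difference between those ranges cannot be told from colour. All 10 leads kept their direction in both runs, and 8 of the 10 had a Fisher's exact p under 0.05 in each run taken alone. The leads were picked for small p over all birds, most of them in these runs, so this is no independent test. The exceptions were the first Z lead in run 1 (16.7% against 8.77%, p = 0.271) and the chromosome 4 lead in run 3 (38.2% against 55.1%, p = 0.119). Fisher's exact test on allele counts treats the alleles of a bird as independent, so its p is too small at leads with missing heterozygotes. Run 1 also holds both near-identical pairs of white-earlobe birds, 1 and 29 and 28 and 30, which were kept here. The chromosome 9 lead at 7072468 stood at 40.4% against 1.79% in run 1 (p = 2.71e-07) and at 26.3% against 6.34% in run 3 (p = 0.00130). With terms for the runs in a linear model, 10 SNPs passed Bonferroni and 5 of these lay on chromosome 9, at 5783015, 5884639, 5896387, 7072468 and 8096789. Of the 10, 2 were among the 39 of the allelic test, those at 5884639 and 7072468. The smallest p of that model was 5.04e-10, at 5884639, where the minor allele was at 39.5% ± 3.46 (SE, n = 100) in white-earlobe birds and 16.0% ± 2.59 (SE, n = 100) in red-earlobe birds. The SNPs of the linear model were chosen after their values were seen. Run 2, with birds of 1 colour, adds to the error of the linear model but not to its contrast of colours. The p-values of the linear model can thus be too small at SNPs that vary little in run 2. Its autosomal inflation factor was 1.33. In the mixed model with terms for the runs 1 SNP passed Bonferroni, the one at 5884639 on chromosome 9.

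**Figure D2:**
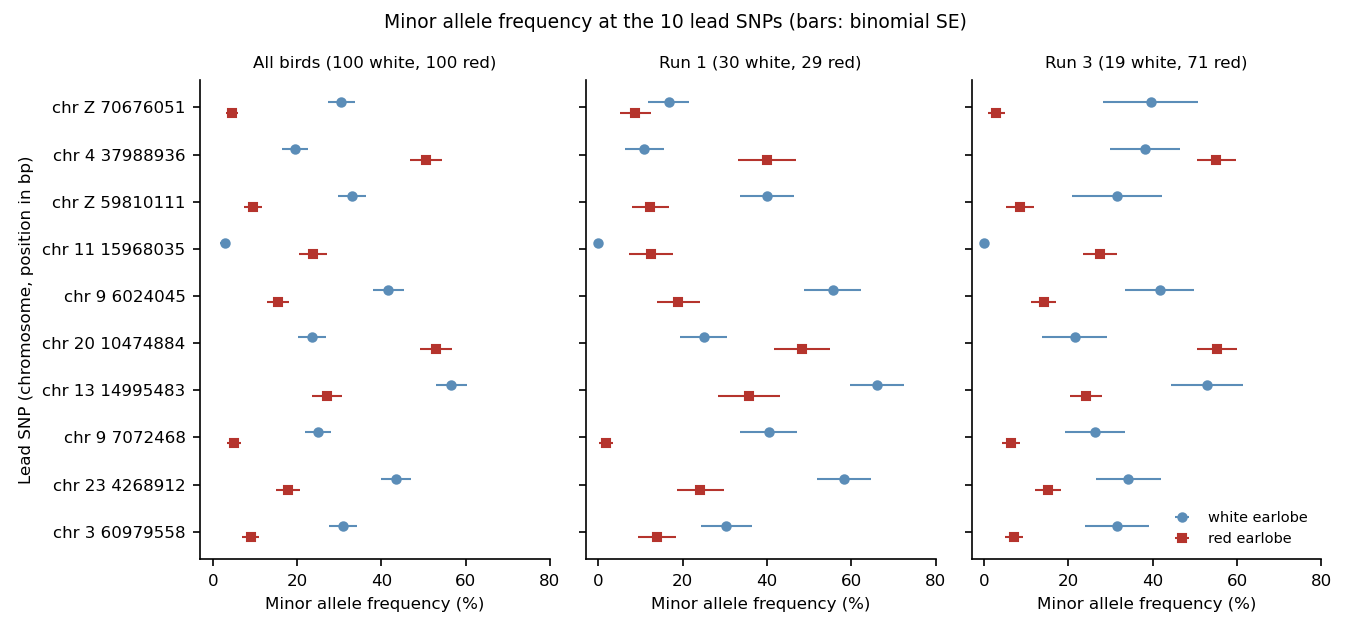
Minor allele frequency in percent at the lead SNPs of the 10 regions with the smallest p, in white-earlobe birds (blue circles) and red-earlobe birds (red squares), with binomial standard errors, over all birds and within runs 1 and 3 of bird numbers, where birds with few heterozygous Z calls count with 1 allele on Z. The colours differ in the same direction in all 3 panels at each SNP.

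**Figure D3:**
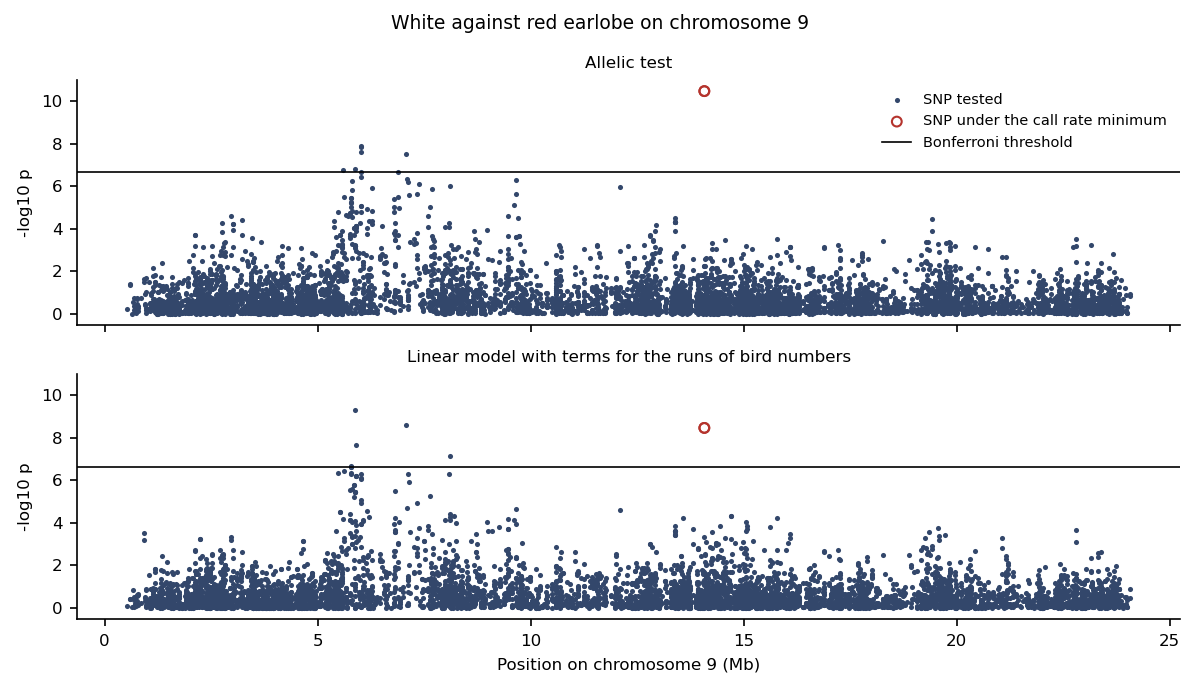
P (as -log10) of each chromosome 9 SNP against its position in Mb, from the allelic test (top) and from a linear model with terms for the runs of bird numbers (bottom), with open circles for 2 untested SNPs called in under 80% of birds and a line at the Bonferroni threshold. The tested SNPs past the threshold lie between 5603095 and 7072468 in the allelic test and between 5783015 and 8096789 in the linear model, and the untested pair lies above the line in both.

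Chromosome Z carried 13.1% of the 1765 SNPs past the false discovery rate but 2.61% of the tested SNPs (Fisher's exact test, adjusted p = 4.17e-88). Chromosome 9 carried 7.25% of the calls and 3.02% of the tested SNPs (adjusted p = 6.82e-18). Chromosomes 3, 10, 20 and 23 also had more calls than their share, with adjusted p from 0.00396 on chromosome 20 to 0.0387 on chromosome 23. Chromosomes 1, 2, 5, 12 and 15 had fewer. In all, 29 chromosomes were compared, and linked SNPs are not independent, so these p-values describe the distribution. With 1 SNP per 10 kb only chromosomes 9 and Z had more than their share, and with 1 allele per single-Z bird chromosome 13 took the place of Z among the 6. With terms for the runs of bird numbers only chromosomes 9 and 22 had more than their share of 108 calls.

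Between the colours, FST, the share of allelic variance that lies between groups, was 0.00381 ± 8.91e-05 (SE over 946 blocks of 1 Mb) on the autosomes and 0.0104 ± 0.000835 (SE over 82 blocks) on Z, where it was 0.00584 with 1 allele per single-Z bird. It was 0.0110 on the autosomes and 0.00937 on Z within run 1, and 0.00730 and 0.0159 within run 3, with 1 allele per single-Z bird. Among 8416 windows of 100 kb, the highest FST was 0.102 on Z from 71100001 to 71200000, inside the first Z region, above the highest window of every shuffle (0.0780). The window on Z from 39900001 to 40000000 had 0.0733, just above the 5% limit of 0.0722, and it did not pass with another 100 shuffles. The next were chromosome 17 from 10200001 to 10300000 (0.0693), chromosome 9 from 5700001 to 5800000 (0.0623) and Z from 66600001 to 66700000 (0.0597), none of which passed. Among windows of at least 10 SNPs, which leaves out the Z windows with 8 SNPs each, the chromosome 9 window passed. Within runs 1 and 3, the chromosome 17 window had 0.142 and 0.165 and the chromosome 9 window 0.194 and 0.0443. Within those runs, with 1 allele per single-Z bird, the highest Z window had 0.0403 and 0.111.

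Of the first 5 principal components of 38656 autosomal SNPs, the first, with 1.67% of the variance, differed between white-earlobe and red-earlobe birds by -0.429 SD (permutation test, adjusted p = 0.0135). The adjusted p of the other 4 ranged from 0.384 to 0.655. Within run 1 the first component differed by -1.06 SD (permutation test, adjusted p = 0.000400) and within run 3 by -0.464 SD (adjusted p = 0.230). The genomic inflation factor, the median chi-square over its value with no difference, was 1.70 ± 0.0332 (jackknife SE) on the autosomes and 3.09 ± 0.241 on Z. Shuffled labels gave medians of 1.18 and 1.62 and at most 1.32 and 2.38. Shuffles within the runs of bird numbers, added later, gave medians of 1.27 and 1.99 and at most 1.41 and 2.62. Of 19900 pairs of birds, 180 had a genomic relationship over 0.2. The mean relationship was -0.00287 within white-earlobe birds, -0.00288 within red-earlobe birds and -0.00793 between the colours.

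Heterozygous calls on Z made up 10.6% ± 11.8 (SD, n = 100) in white-earlobe birds and 9.80% ± 12.6 (SD, n = 100) in red-earlobe birds, a difference that did not pass (permutation p = 0.629, two-sided, adjusted p = 0.927). White minus red was -1.05 points in run 1 (permutation adjusted p = 0.266) and 1.28 points in run 3 (permutation adjusted p = 0.000540). Without white-earlobe birds 83 and 88, which lay between 5% and 20%, the difference in run 3 was 0.529 points (permutation p = 0.00240). The birds fell into separate clusters. Below 15% lay 69 white-earlobe and 72 red-earlobe birds, with a median of 2.15%, and above it 31 and 28 birds, with a median of 29.2% (Fisher's exact p = 0.757 for the shares). All 30 white-earlobe birds and 28 of the 29 red-earlobe birds of run 1 lay above, so this class and the run largely coincide. On the autosomes, 25.7% ± 1.83 (SD, n = 100) of calls were heterozygous in white-earlobe birds and 25.3% ± 1.26 (SD, n = 100) in red-earlobe birds, a difference that did not pass (permutation p = 0.0593, two-sided, adjusted p = 0.178 over the 3 measures per bird). White minus red was -0.680 points in run 1 and 0.625 points in run 3 (permutation adjusted p = 0.138 for both).

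**Figure D4:**
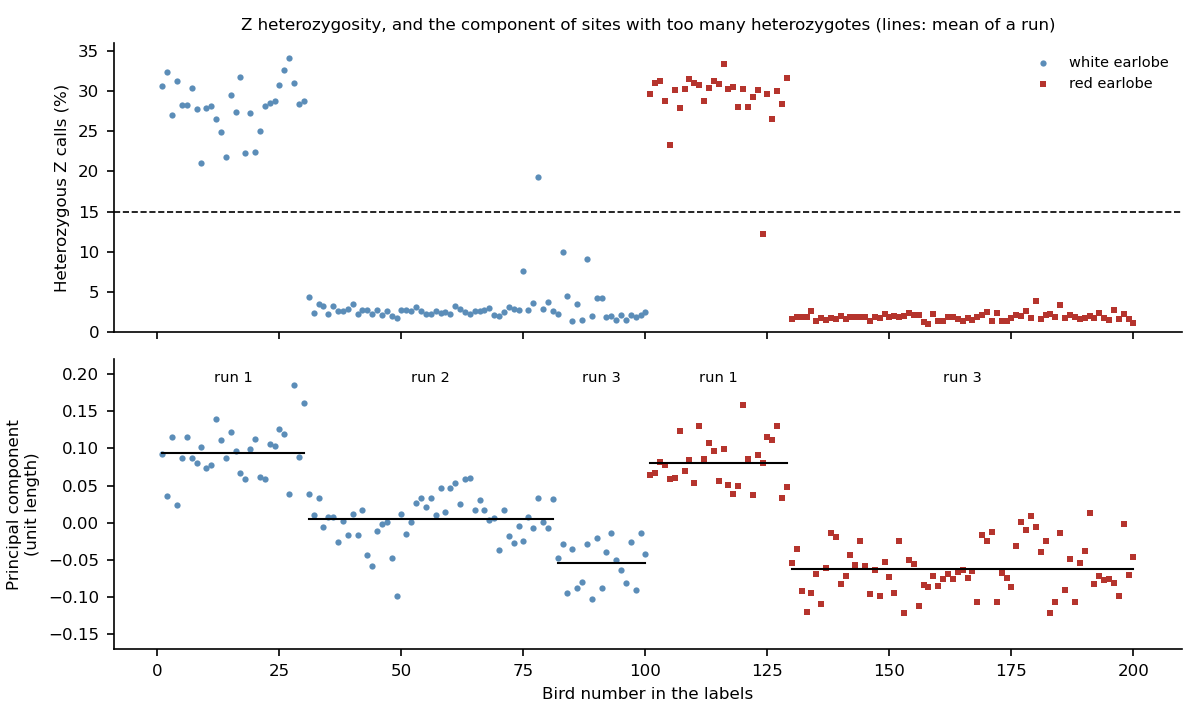
Share of heterozygous Z calls in percent (top) and principal component of the SNPs with too many heterozygotes (bottom) for each bird, against the bird's number in the labels; blue circles are white-earlobe and red squares red-earlobe birds, the dashed line is at 15% and the black lines are the means of the runs. Z heterozygosity separates 59 birds above the line from 141 below it, and the component steps at birds 31, 82, 101 and 130.

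The authors' deposited table gives 1 p-value for each of the 223796 SNPs, with 1 missing. Their values equalled the recomputed allelic chi-square p to within 1% at 223791 of 223795 SNPs, or 99.998%. The match was 17.3% for the trend test, 17.0% for logistic regression, 2.95% for Fisher's exact test and 2.00% for the genotypic test. The smallest p in the authors' deposited table was 1.41e-11, and 39 of its SNPs passed Bonferroni, the same SNPs as in the recomputed test.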

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

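Of the tests in this part, those of runs of bird numbers, of single Z copies, of maternal lineage, of copies of a sequence, of the Z class at the leads, of kinship and of heterozygote loss, and the second set of shuffles, were chosen only after the results were seen. The first shuffles of the colour labels were planned.

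At 2 of the 10 lead SNPs the difference between colours was itself different in birds with few and with many heterozygous Z calls (permutation of that class within colours, adjusted over the 10 leads). At Z 70676051 the rarer allele was at 37.0% in white-earlobe and 2.86% in red-earlobe birds with few heterozygous Z calls, and at 16.1% and 8.93% in the others (adjusted p = 0.0476). At chromosome 9 position 7072468 the values were 18.8% and 6.25% in birds with few, and 40.7% and 1.85% in the others (adjusted p = 0.0106). The class nearly coincides with run 1 of the bird numbers, so class and run cannot be separated here.

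A pair of SNPs at chromosome 9 positions 14077358 and 14077368 were called in 76.5% of birds, under the minimum, and were therefore not tested, and the authors' deposited table has no p-value for them. They were the only SNPs under this minimum in the deposited genotypes, and why they were kept there is not known. Both had the rarer allele at 54.7% in white-earlobe and 18.4% in red-earlobe birds, with an allelic p of 3.43e-11 each. The genotype counts of each colour were the same at both, so the pair is not separate evidence. With terms for the runs the p was 3.38e-09. Heterozygotes were far fewer than Hardy-Weinberg proportions give (exact p = 4.64e-18), and the trend test gave 3.38e-07.

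The 39 SNPs past Bonferroni, the 1765 past the false discovery rate and the highest FST window of 0.102 were each set against 100 shuffles of the colour labels. Of the 101 splits, the real one included, only 1, the real one, gave a result as large in each case. The highest other values were 5 SNPs, 26 SNPs and 0.0780. No shuffle thus reached the counts as a whole, which does not hold for each SNP. The shuffles treat the birds as interchangeable, although 180 of 19900 pairs had a genomic relationship over 0.2. Another 100 shuffles, added later, gave up to 6 SNPs, 60 SNPs and a window of 0.0983, so the highest values vary with the draw and the window exceeded them narrowly. Shuffles kept within the runs, added later, gave up to 8 and 139 SNPs (medians 3 and 32), below the real counts, but 1 of the 50 gave a smallest p of 4.43e-12, under the real 1.41e-11, and their 5% threshold of 6.19e-10 was passed by 1 SNP.

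Small p-values were more common on Z than on the autosomes, with allelic inflation factors of 3.09 and 1.70. Single Z copies counted as 2 alleles may account for part of this, since with 1 allele for each bird of low Z heterozygosity the Z factor was 1.78 ± 0.154 (jackknife SE). They are argued against as the whole cause. The trend test, which allows for them, gave 1.85 ± 0.111 on Z and 1.46 ± 0.0166 on the autosomes. Differences between runs of bird numbers are argued against likewise, with 1.56 ± 0.110 and 1.33 ± 0.0152 with terms for runs. Such terms do not take up differences between the separate number ranges that the colours hold within a run. Kinship cannot be told apart, since in the mixed model the factors were 1.05 ± 0.0664 and 0.998, but with runs they were 1.17 and 0.995, and the variance share of kinship lay at the top of the values tried. A link of Z to earlobe colour was not tested apart from the comparison of the groups.

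Besides Z, 6 SNPs past Bonferroni under the trend test differed between colours in birds of low Z heterozygosity (Fisher's exact p of carriers up to 7.86e-09). In birds of high Z heterozygosity they did not pass (p from 0.409 to 1), a contrast that was itself not tested. Of 59 such birds, 58 carried the rarer base on chromosome 10, 57 on W and 53 on an unplaced sequence (position 1311). On chromosome 4 there were 16 carriers, on chromosome 19 only 1 and on chromosome 23 none. Except on chromosome 4 the carrier state thus varied little in these birds, and a difference could hardly pass. The SNPs on chromosomes 4, 10 and W and the unplaced sequence were among the 740 that defined the runs, so runs were found again without each SNP's own sequence. At 3 of the 6, on chromosomes 4, 10 and 23, carriers then differed between white-earlobe birds of runs 2 and 3 (p from 3.33e-14 to 0.00116). These birds share colour and Z class. Between colours in run 3 carriers did not differ past the limit of 0.00833, with p = 0.0368 on chromosome 10. On chromosome 23 this was fixed, since no bird of run 3 carried the rarer base. On chromosome 4 all 19 white-earlobe birds of run 3 carried it, so the excess in red-earlobe birds seen over all birds could not arise there. Run 3 thus says little about colour at these 2 SNPs. A difference between runs may explain the SNPs on chromosomes 4, 10 and 23, but its kind is not given by the labels and was not tested. At 2, on chromosome 19 (position 3930351) and the unplaced sequence, carriers differed between colours within run 3 (p = 3.47e-06 and 2.02e-06). This argues against differences between runs as the whole cause there, though not against differences between number ranges within run 3. The rarer base on chromosome 19 also varied by run. It was absent in run 1, at 45.0% in white-earlobe birds of run 2, and at 58.3% in white-earlobe and 15.5% in red-earlobe birds of run 3. The SNP on W (position 4994686) passed in neither comparison (p = 0.154 and 0.0132). Reads shared between copies of a sequence may lie behind the 4 SNPs on chromosomes 4, 10 and W and the unplaced sequence, which had 102 to 154 heterozygotes and no bird homozygous for the rarer base, the one on W in 57 of 59 birds of high Z heterozygosity; they are argued against on chromosome 19, with 13 such homozygotes, and stay open on chromosome 23, where Hardy-Weinberg proportions give 0.72. Maternal lineage cannot be told apart with 5 mitochondrial sites, where the largest absolute correlation with carrier state was 0.241, and a difference tied to earlobe colour stays open, untested.

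On chromosome 9 all 8 SNPs past Bonferroni were more frequent in white-earlobe birds. Differences between the 3 runs of bird numbers are argued against. The difference between colours within runs was 1.22 times that over all birds (median, from 0.928 to 1.47). Within a run the colours hold separate ranges of bird numbers, so a difference between those ranges cannot be told from colour. Autosomal FST was also higher within runs (0.0110 in run 1 and 0.00730 in run 3) than over all birds (0.00381). Heterozygotes read as homozygotes raise the allelic chi-square. They are argued against as the whole cause at the 2 SNPs in Hardy-Weinberg proportions, with a trend test adjusted p of at most 0.00682. At the other 6 they stay open, although these passed the false discovery rate under the trend test too (adjusted p of at most 0.0405). The trend test does not allow for a loss that differs by colour. The lead at 6024045 was called in 90 white-earlobe and 100 red-earlobe birds. All 8 SNPs were picked for small p in the same birds, and the autosomal inflation factor of the trend test was 1.46. Among the 8, only the one at 7072468 passed Bonferroni under the trend test (p = 1.47e-07). Kinship cannot be told apart, since all 8 SNPs had a p of at most 0.000502 in the mixed model and 0.00481 in that with runs, but were picked for small p-values, and over the genome 5 SNPs of chromosome 9 passed the false discovery rate with runs and 0 without, where 2 SNPs elsewhere passed and 11577 had an unadjusted p under 0.05. A variant for earlobe colour in this part of chromosome 9 is thus a hypothesis that these data leave open.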

How the results depend on the processing

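The settings that use runs of bird numbers or single Z copies, that leave out near-identical or very heterozygous birds or birds of intermediate Z heterozygosity, the inflation factors with Z heterozygosity, and the second set of shuffles were chosen after seeing the data. The counts of 39 and 1765 SNPs and of 20 leads past Bonferroni depended on the test. They were 8, 135 and 3 under the trend test, 10, 113 and 3 with 5 principal components, 2, 2 and 1 in the mixed model, 13, 213 and 5 with Z heterozygosity as a covariate and 12, 208 and 5 with call rate as a covariate. Under genomic control they were 0, 0 and 0, with 11242 SNPs at an unadjusted p under 0.05. With terms for runs they were 10, 108 and 1, and in the mixed model with runs 1, 5 and 0, with 11280 SNPs at an unadjusted p under 0.05. Run 1 alone gave 3, 77 and 0 and run 3 alone 20, 475 and 2, with fewer birds and 2 alleles on Z. With a single Z allele run 3 alone gave 14, 207 and 1. A single Z allele gave 23 SNPs past Bonferroni, all on autosomes. The false discovery rate count was 1045 with a call rate of at least 0.9, 995 without SNPs out of Hardy-Weinberg proportions and 640 with 1 SNP per 1 kb, each with fewer SNPs tested. Fisher's exact test (40 and 1426 SNPs), the authors' deposited p-values, and leaving out near-identical or very heterozygous birds stayed within 1.5 times. The lower frequency filters and the removal of birds with call rate under 0.7 removed nothing. Each of the 10 named leads kept its direction in all 15 settings. For Fisher's exact test and genomic control this was fixed, since they take the direction of the allelic test. The leads were picked for small p in the same birds, so this is no independent test. Except where stated, the cause was not tested.

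The autosomal inflation factor of 1.70 was 1.66 with 1 SNP per 10 kb, 1.46 in the trend test, 1.39 with principal components, 1.43 with Z heterozygosity, 1.33 with runs, 0.998 in the mixed model and 0.995 in the mixed model with runs. The Z factor of 3.09 was 1.85, 1.87, 1.84, 1.56, 1.05 and 1.17 in the trend test, with principal components, with Z heterozygosity, with runs, in the mixed model and in the mixed model with runs, and 1.78 with a single Z allele. Autosomal FST was 0.00327 with a call rate of at least 0.9, 0.0110 in run 1 and 0.00730 in run 3. FST on Z was 0.00584 with a single Z allele, 0.00937 in run 1 and 0.0159 in run 3. Past the FST limit lay 1 window with at least 10 SNPs, on chromosome 9 and not among the 2, and 1 of the 2 with another 100 shuffles. With windows of 50 kb there were 3, 2 of them on chromosome 9. Chromosomes with more calls than their share fell from 6 to 2 with 1 SNP per 10 kb and to 2 with runs, chromosomes 9 and 22. The first principal component did not pass in run 3 (adjusted p = 0.230). Z heterozygosity differed between colours in run 3, by 1.28 points (p = 9.00e-05), and by 0.529 points without birds between 5% and 20%. Shuffles within runs gave at most 8 SNPs past Bonferroni, against 5. The candidate gene lists, with their 3 alternatives, were not run. No paired analysis was possible because the colours share no bird numbers. Genotype depth may limit the allelic results, since lost heterozygotes raise the allelic chi-square, but it is unknown and was not tested.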

Other observations

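The tests of birds and sites in this part were chosen after the values were seen. The 5 mitochondrial sites, which follow the maternal line, did not differ between colours past the threshold in Fisher's exact test of carriers. At site 14390 the rarer base was called alone in 8 white-earlobe and 19 red-earlobe birds, and at site 14204 in 8 and 2. Fisher's exact p of carriers ranged from 0.0494 to 1 over the 5 sites, and the smallest adjusted p was 0.0930.

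Linkage was uneven among the SNPs of a region. In the chromosome 9 region from 5603095 to 6024058, the other 5 SNPs had a median r squared of 0.461 with the lead and at most 0.990, and in the chromosome 20 region the other 3 had a median of 0.105 and at most 0.663. The 2 SNPs of the Z region at 59810111 were completely correlated (r squared 1).

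At chromosome 7 position 13721503, which passed Bonferroni with terms for the runs (p = 9.56e-08) but not in the allelic test (p = 1.42e-05), the minor allele was at 55.6% in white-earlobe and 5.80% in red-earlobe birds of run 3 (Fisher's exact p = 1.13e-10). In run 1 it was at 21.4% and 15.5% (p = 0.474). At chromosome 3 position 13117416 it was at 51.7% against 20.7% in run 1 and at 31.6% against 8.45% in run 3.

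White-earlobe birds 1 and 29 had identical genotypes at 93.9% of 213700 SNPs called in both, with opposite homozygotes at 0.333%, and white-earlobe birds 28 and 30 at 88.9% of 200140 SNPs, with opposite homozygotes at 0.997%. Among 300 random pairs of birds the median was 55.4% and the highest 63.1%. The next closest pair, red-earlobe birds 126 and 127, had 73.9%. Without birds 29 and 30 the SNPs past Bonferroni numbered 38, of which 36 were among the 39.

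White-earlobe birds 78 and 88 had 36.4% and 30.8% heterozygous autosomal calls, above the group's mean of 25.7%. Bird 78 lay at 19.3% on Z, between the clusters, as did white-earlobe birds 75 (7.57%), 83 (10.0%) and 88 (9.09%) and red-earlobe bird 124 (12.2%).

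Among white-earlobe birds of low Z heterozygosity, 50 of run 2 and 19 of run 3 differed past Bonferroni at 8 SNPs under the trend test, 2 of them on W, 2 on unplaced sequences and 4 on autosomes, against at most 1 in 50 shuffles of these birds. The smallest p was 7.19e-14. Of the 8 SNPs, 4 were among the 740 that defined the runs, and the shuffles did not repeat the search for runs, so part of the difference was built in. With runs found without the SNP's own sequence, 6 SNPs passed, all among the 8, and the 2 on W did not. The autosomal inflation factor of that comparison was 1.02.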
